A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

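Total RNA of rabbit endometrial stromal cells was depleted of ribosomal RNA and made into strand-keeping libraries for Illumina sequencing, per the labels' protocols. The labels gave 3 control and 3 poly(I:C) libraries, numbered 1 to 3 in each group, and gave no dose, time or animal. HISAT2 2.0.4, StringTie 1.3.1, Cufflinks 2.2.0 and DESeq 1.10.1 and the genome build OryCun2.0 are named in the submitters' processing notes, without the role of each. The transcript names are of the form that StringTie gives.

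The deposited table held FPKM values made by the authors, with 1 column per library and only lncRNA transcripts as rows. The denominator of the FPKM, the filter that defined an lncRNA and whether reads were counted by strand are not given in the sources used here. Exon coordinates of the lncRNAs, and of 4138 newly assembled genes with 6474 transcripts, were taken from the deposited annotation, per the file headers. Chromosome numbers were assigned from the RefSeq sequence names of the build. The files named no neighbouring or host gene, and the gene table at hand was of another assembly, mOryCun1.1, whose coordinates were not used. For that reason the gene lists fixed beforehand (interferon-stimulated genes, double-stranded RNA sensing, inflammation, antigen presentation, cell death, cell cycle, decidualization, extracellular matrix, stress, and markers of epithelial, endothelial, leukocyte and muscle cells) could not be tested, and levels of protein-coding genes were not analysed here.

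Depth was recovered from the values. FPKM multiplied by exonic length was a multiple of a fixed step in each library, taken as what 1 covered base is worth. Between 61.2% and 66.9% of 1178 to 1346 low values per library were whole multiples within 0.1. The step was chosen as the best fitting, so the 20.0% of an arbitrary step is not its chance value, and the next best step gave 36.0% to 50.7%. The depths rest on this choice. With it, the commonest values were 600, 300 and 150 bases in every library, and a pair was taken as 300 bases. The totals were 13.3, 14 and 12.5 gigabases in control replicates 1 to 3 and 13.6, 13.5 and 12.8 gigabases in poly(I:C) replicates 1 to 3. The median transcript had 2.97 read pairs in a library, so most listed lncRNAs were too shallow to test. No pair of libraries shared a value above 0. The intervals given cover counting or sampling error only. Summed FPKM ran from 20006 to 76479 per library and was set by 3 loci, so the columns were not rescaled to a common sum.

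Transcripts with at least 0.5 FPKM in at least 3 of the 6 libraries were tested, whatever their group. Values were log2(FPKM + 0.5) and were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend, no covariate, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Log2 changes are on that scale and understate the change of low transcripts, while changes given as N-fold are ratios of mean FPKM. The same fit was made on FPKM summed over the listed lncRNA transcripts of each locus. The planned lncRNA classes were replaced by a match of exons to a newly assembled transcript, after the files were seen, since no other annotation of this build was used. Fisher's exact test and permutation tests of medians (100000 resamples, 20000 under the alternatives) used SciPy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots used matplotlib 3.10.9.

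The transcripts named in the text were set by a rule made before the data were examined. Among called transcripts whose groups did not overlap, it took the 8 largest rises and 8 largest falls and the 4 most abundant in each direction, which gave 17 transcripts, and the 4 loci with the largest rise and the 4 with the largest fall. Others are named as chosen after their values were seen.

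The limma fit was tested on simulated data with the depth of these libraries, a dispersion of 0.1 and 200 changed transcripts. For transcripts, 35.4% of 2-fold and 94.7% of 4-fold changes were recovered among 1016 tested, and 6.40% of calls were false. For loci, 23.9% and 88.5% were recovered among 1107 tested, and 6.02% of calls were false. For the share of a locus held by a transcript, 91.9% of 8-fold changes were recovered among 313 tested. The permutation tests of medians and of neighbouring loci were also tested on simulated data.

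The alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 1 FPKM, centring each library on its median, quantile normalization, limma without trend or with robust variances, the replicate number as a block, stricter thresholds and each library left out. Added after the data were seen were a mean of at least 3000 covered bases and leaving out transcripts that span over 100 kb.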

Results

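Long non-coding RNAs (lncRNAs) were measured by RNA sequencing in cultured endometrial stromal cells of New Zealand white rabbits. Stromal cells are the fibroblast-like cells of the uterine lining. The 6 libraries fell into 2 groups, 3 from unstimulated control cells and 3 from cells stimulated with poly(I:C), a synthetic double-stranded RNA that cells sense as they sense viral RNA. The deposited values were FPKM (fragments per kilobase of transcript, scaled to the fragments sequenced) of 10927 assembled lncRNA transcripts at 8177 loci. The transcripts had a median exonic length of 628 bp, and 73.58% had 2 exons. Between 7345 and 7543 transcripts lay above 0 in each library, and 1022 to 1229 reached 0.5 FPKM. The FPKM steps gave a depth of 12.5 to 14 gigabases per library, with means of 13.3 gigabases in both groups. At a transcript of median length, 0.5 FPKM then stood for about 13.9 read pairs of 300 bases, with a counting error of 26.8%. Log2 FPKM values correlated across transcripts with r of 0.767 to 0.868 between libraries of a group and 0.671 to 0.798 between groups, and transcripts are not independent replicates. The first principal component held 34.0% of the variance and placed all 3 control libraries on the other side of 0 from all 3 poly(I:C) libraries. The second held 26.5% and did not separate the groups. On it control replicate 2 lay below 0 with poly(I:C) replicates 1 and 2. Control replicates 1 and 3 lay above 0 with poly(I:C) replicate 3, and the cause was not tested.

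The comparison of stimulated with unstimulated cells asked which lncRNAs take part in the response to poly(I:C). Among transcripts whose change was called, more rose than fell: 73 were higher and 15 lower under poly(I:C). The largest rise was that of MSTRG.92782.1 on chromosome 15, which was listed at 0 in all 3 control libraries and reached 51.8 ± 8.58 FPKM (SD, n = 3) under poly(I:C). MSTRG.76011.3 on chromosome 13 rose 26.4-fold, from 1.08 ± 0.193 to 28.5 ± 3.04 FPKM (SD, n = 3 each). MSTRG.154331.1, on an unplaced scaffold, was the most abundant transcript that rose and went from 20.3 ± 5.76 to 138 ± 12.1 FPKM. The largest fall was that of MSTRG.113657.1 on chromosome 21, which was 20.1-fold lower, at 14.1 ± 2.56 FPKM in control and 0.700 ± 0.0328 FPKM in stimulated cells.

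These calls came from limma on log2(FPKM + 0.5), two-sided, at a Benjamini-Hochberg adjusted p below 0.05, over the 931 transcripts with at least 0.5 FPKM in at least 3 libraries. Of these, 88 passed and 213 had an unadjusted p below 0.05. In all 88 the values of the groups did not overlap. Over all tested transcripts the groups did not overlap for 277 (29.75%), where chance gives 10%. The median change was 1.34 on the log2 scale among the rises and -1.03 among the falls, and 60 rises and 8 falls were at least a doubling or halving. Over all 931 tested transcripts the median change was -0.0584, so the tested transcripts as a whole did not shift upward. The rises began from a median of 0.138 FPKM in control cells, so that most of the transcripts that rose were near the floor of the scale before stimulation, where the pseudocount makes the fold change understate the difference. The count was 53 without control replicate 2, the 15 falls became 6, 4 and 6 without control replicates 1, 2 and 3, 9 without poly(I:C) replicate 2 or 3 and 5 with no filter, and the labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries.

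All coordinates are on the rabbit build OryCun2.0, and the files do not pair these transcripts with named genes. MSTRG.92782.1 has 2 exons with 264 bp in all, spread over 102195140 to 102442631 on the plus strand of chromosome 15. Thus MSTRG.92782.1 has less exonic length than the 300 bases taken as a read pair. Its change was 6.70 ± 0.18 (SE) on the log2(FPKM + 0.5) scale, with an adjusted p of 2.25e-05 by limma, and the 3 poly(I:C) libraries held 47.0, 46.7 and 61.7 FPKM. Because all control values were 0, that number depends on the pseudocount and no fold is given. MSTRG.76011.3 has 3 exons and 5797 bp within 75298422 to 75497510 on the minus strand of chromosome 13, and its change was 4.20 ± 0.19 (SE; limma adjusted p = 2.28e-04). MSTRG.154331.1 has 2 exons within 1245 to 2033 on the minus strand of its scaffold, and its change was 2.77 ± 0.29 (SE; limma adjusted p = 0.00262). MSTRG.104681.2, at 37300991 to 37327486 on the minus strand of chromosome 18, held 0.635, 0 and 0 FPKM in the control libraries and 2.91, 7.70 and 11.5 FPKM in the poly(I:C) libraries. Its change of 3.40 ± 0.56 (SE) had a limma adjusted p of 0.0143, which became 0.0616 without control replicate 2, 0.0617 without control replicate 3 and 0.0593 without poly(I:C) replicate 2. With the replicate number as a block, the limma adjusted p was 0.0862. MSTRG.104681.2 has 2 exons with 311 bp in all. The locus MSTRG.104682 lies within its intron on the same strand, so it does not overlap these exons. Another transcript numbered at MSTRG.104681 is not listed, and whether it shares reads with MSTRG.104682 is unknown.

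The other named rises went from almost no signal to between 1.94 and 3.55 FPKM in each poly(I:C) library. MSTRG.24217.5 (chromosome 3), MSTRG.43056.1 (chromosome 7, 134001706 to 134004357), MSTRG.13599.2 (chromosome 2, 77094256 to 77098444) and MSTRG.114484.1 (chromosome 21, 11826019 to 11828841) had changes of 2.74, 2.71, 2.56 and 2.51 on the log2 scale, in that order. Their highest value in any control library was 0.149 FPKM, in MSTRG.114484.1, and their limma adjusted p lay between 3.05e-04 and 0.00189.

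The locus MSTRG.24217 rose as a whole. It spans 94535916 to 94598984 on the plus strand of chromosome 3 and holds 28 listed lncRNA transcripts, of which 6 were tested and rose. Transcripts this low in control cells passed the filter through their poly(I:C) values, so the filter largely fixed the direction of these 6. The others did not reach 0.5 FPKM in at least 3 libraries and were not tested, though they count in the sum of the locus. Their changes ran from 0.97 for MSTRG.24217.19 to 2.74 for MSTRG.24217.5, with limma adjusted p from 3.05e-04 to 0.0401. Summed over its listed transcripts the locus went from 2.97 ± 0.767 to 22.5 ± 3.03 FPKM (SD, n = 3 each), a change of 2.75 ± 0.22 (SE; limma adjusted p = 3.60e-04). At MSTRG.117135 on the X chromosome (50569659 to 50598963) and MSTRG.81389 on chromosome 14 (17821714 to 17822771), the 2 tested of 3 listed transcripts rose at each locus, and the same holds for their direction. These 3 loci were all those with 2 or more called transcripts, and they were named after their values were seen.

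**Figure D1:**
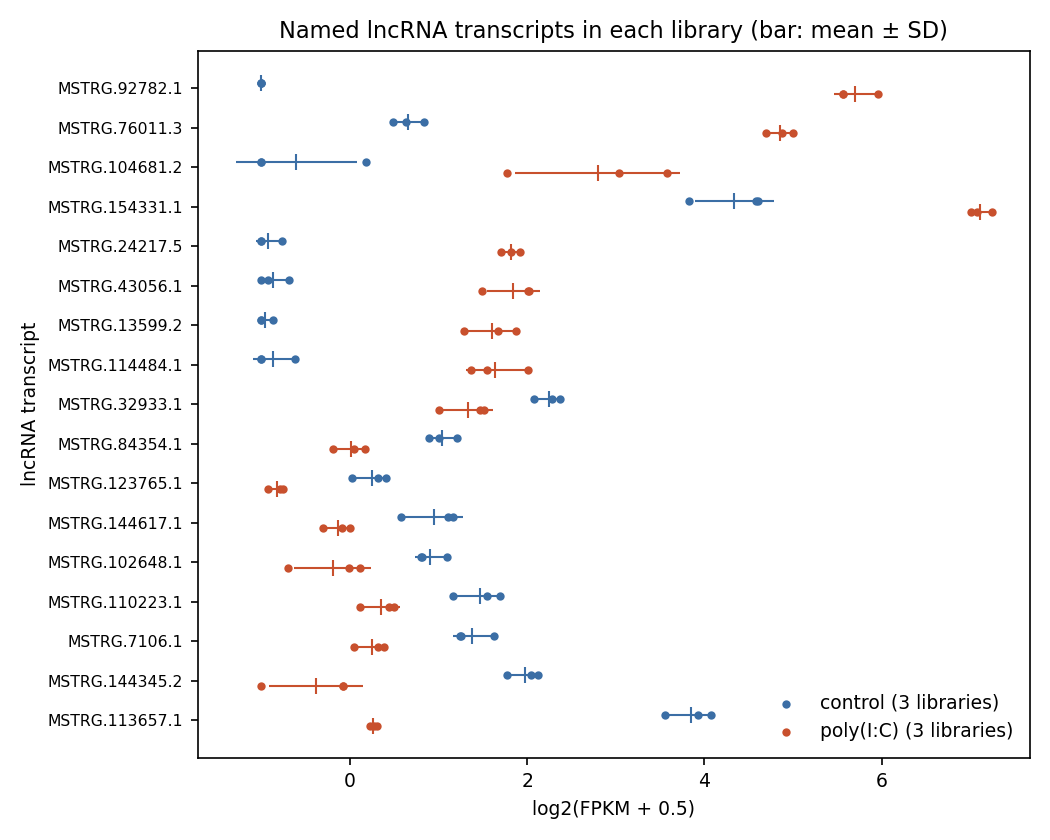
Level of each named lncRNA transcript as log2(FPKM + 0.5) on the horizontal axis, in 3 control libraries (blue) and 3 poly(I:C) libraries (orange). Points are libraries and bars are mean ± SD; the groups do not overlap in any of the 17 transcripts, of which 8 rose and 9 fell.

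The falls were fewer and smaller. After MSTRG.113657.1, the largest was that of MSTRG.144345.2 on an unplaced scaffold (23649 to 39335, minus strand), with 3.87, 2.91 and 3.61 FPKM in control cells and 0, 0.447 and 0.450 FPKM under poly(I:C), a change of -2.36 ± 0.29 (SE; limma adjusted p = 0.00403). MSTRG.32933.1 on chromosome 4 (84385744 to 84388564) was among the most abundant that fell, from 4.25 ± 0.479 to 2.05 ± 0.467 FPKM (SD, n = 3 each), with a limma adjusted p of 0.0458. MSTRG.110223.1 on chromosome 19 (40940354 to 40943429) fell from 2.29 ± 0.512 to 0.787 ± 0.177 FPKM, with a limma adjusted p of 0.0230. MSTRG.7106.1 (chromosome 1), MSTRG.102648.1 (chromosome 17), MSTRG.84354.1 (chromosome 14) and the scaffold transcripts MSTRG.144617.1 and MSTRG.123765.1 fell by 1.03 (MSTRG.84354.1) to 1.13 (MSTRG.7106.1) on the log2 scale, with limma adjusted p of 0.00756 to 0.0461. Leaving out a library ended each of these last 7 calls: any of the 6 for MSTRG.32933.1 and MSTRG.102648.1 (limma adjusted p up to 0.152 and 0.139), any but control replicate 3 for MSTRG.110223.1 (up to 0.0808), any but control replicate 1 for MSTRG.144617.1 (up to 0.0947), control replicate 2 or 3 for MSTRG.123765.1 (0.0721 and 0.0708), control replicate 2 or poly(I:C) replicate 2 for MSTRG.84354.1 (0.0539 and 0.0541), and poly(I:C) replicate 2 for MSTRG.7106.1 (0.0541).

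The locus of the largest fall kept some of its transcripts. MSTRG.113657 lies at 3444057 to 3454147 on the plus strand of chromosome 21 and has 4 listed transcripts, which differ in an intron of 1681 bp at 3448776 to 3450456. MSTRG.113657.1 and MSTRG.113657.3 keep this intron within an exon, and MSTRG.113657.2 and MSTRG.113657.4 have it removed, the latter from 3448790. The transcripts that keep the intron summed to 15.4 ± 0.811 FPKM in control and 0.700 ± 0.0328 FPKM in stimulated cells (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). Those without it summed to 9.30 ± 0.669 and 13.6 ± 3.80 FPKM (exact permutation p = 0.3). Transcripts that keep the intron thus held 62.4 ± 1.08% of the locus in control and 5.15 ± 1.35% under poly(I:C) (SD, n = 3 each; exact permutation p = 0.1). MSTRG.113657.2 alone was at 8.65 ± 0.917 and 9.62 ± 2.15 FPKM, a log2 change of 0.13 (limma adjusted p = 0.801). The sum of all 4 transcripts was 24.7 ± 1.39 and 14.3 ± 3.82 FPKM, a log2 change of -0.81 that did not pass (limma adjusted p = 0.0625). The grouping by intron was chosen after the values were seen.

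**Figure D2:**
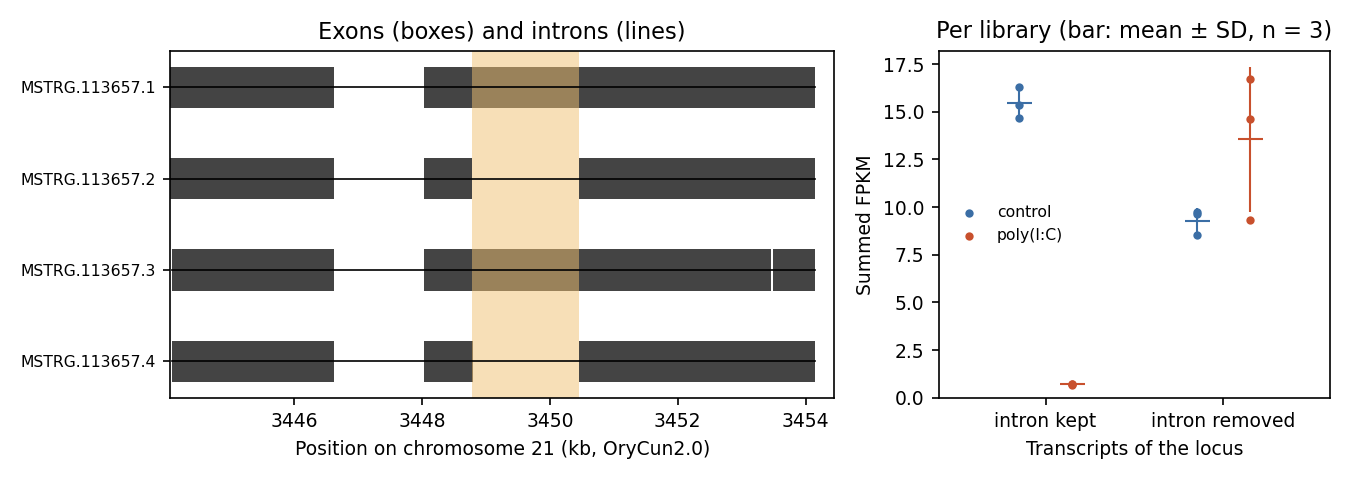
Left, exons (boxes) and introns (lines) of the 4 transcripts of MSTRG.113657 by position on chromosome 21 in kb, with the intron of 1681 bp shaded. Right, FPKM summed over transcripts that keep the intron and over those without it, in 3 control (blue) and 3 poly(I:C) libraries (orange; bars are mean ± SD), where the first fell from 15.4 to 0.700 FPKM and the second stood at 9.30 and 13.6 FPKM.

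Summing the listed transcripts of each locus asked the same of whole loci. The sums still depend on how reads were divided, since FPKM is scaled by the length of each transcript, and reads can be shared with overlapping loci or with transcripts not listed, which the numbering shows at 277 of the tested loci. Of 1062 tested loci, 100 rose and 45 fell by limma at an adjusted p below 0.05, and 304 had an unadjusted p below 0.05. The loci that rose most were MSTRG.92782, MSTRG.76011 and MSTRG.104681, each with a single listed transcript, and MSTRG.31368 on chromosome 4 (55474776 to 55504030, plus strand), which went from 0.268 ± 0.257 to 4.79 ± 1.70 FPKM (SD, n = 3 each; log2 change 2.79 ± 0.33 SE, limma adjusted p = 0.00150). The loci that fell most were MSTRG.144345 with a change of -2.42, MSTRG.153610 (13025 to 14634 on an unplaced scaffold) with -1.62, MSTRG.146677 (147900 to 162150 on another) with -1.41 and MSTRG.110223 with -1.11. MSTRG.104681 and MSTRG.110223 have the same values as their single listed transcripts, MSTRG.104681.2 and MSTRG.110223.1. Under 17 other fits those transcripts lost their call in 4 and 8, and the loci in 0. The loci thus kept their calls only through the set they were fitted and adjusted with, which is no further evidence for either change. MSTRG.146677 stood at 1.3 ± 0.297 FPKM in control and 0.174 ± 0.0653 FPKM in stimulated cells (SD, n = 3 each; limma adjusted p = 0.00206).

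The 88 called transcripts came from 81 loci, of which 74 were also called as loci. All 81 called transcripts of these 74 loci had the direction of their locus. That was largely fixed in advance. Of the 88 called transcripts, 47 were the only transcript listed at their locus, and the others are part of the sum. Another 71 called loci had no called transcript. Among the called loci 68.97% rose (95% exact binomial interval 60.8 to 76.4%), against 82.95% of the called transcripts (73.4 to 90.1%). Called loci lay on all 21 autosomes, the X chromosome and unplaced scaffolds, with 80 rises and 35 falls on chromosomes and 20 rises and 10 falls on scaffolds. The count of called loci was 95 without control replicate 2 (82 rose, 13 fell) and 94 without poly(I:C) replicate 1 (76 rose, 18 fell). The falls were also fewer without control replicate 1 (87 rose, 16 fell) and without poly(I:C) replicate 2 (80 rose, 21 fell), so the share of rises rests in part on single libraries.

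**Figure D3:**
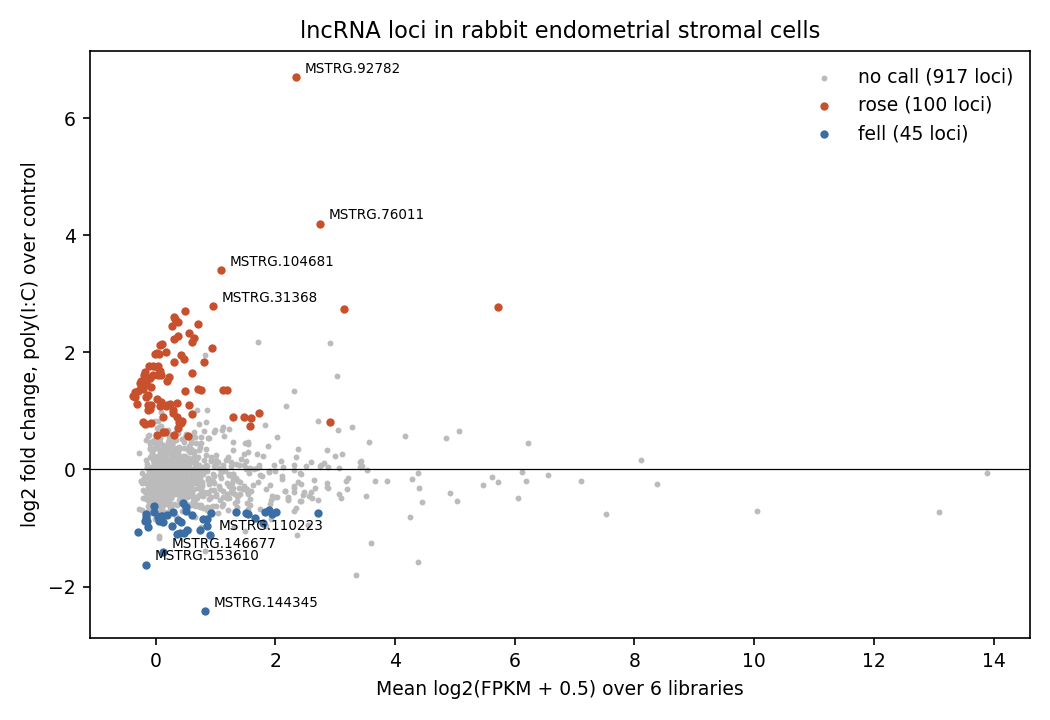
Log2 fold change of poly(I:C) over control against mean log2(FPKM + 0.5) over the 6 libraries for 1062 lncRNA loci, one point each. Orange points are the 100 loci that rose, blue the 45 that fell and grey those not called; the 4 largest rises and 4 largest falls are named, from 6.70 for MSTRG.92782 to -2.42 for MSTRG.144345.

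Some lncRNAs were listed only after stimulation. At 0 in all 3 control libraries and above 0.5 FPKM in all 3 poly(I:C) libraries were 10 transcripts, and none showed the reverse. After MSTRG.92782.1, the most abundant were MSTRG.23678.2 on chromosome 3 (82362449 to 82368397), with 2.50, 1.61 and 2.85 FPKM in the poly(I:C) libraries, and MSTRG.32118.5 on chromosome 4 (75246429 to 75356662), with 1.21, 1.13 and 1.55 FPKM. The other 7 had means of 0.639 to 0.931 FPKM. These were named after their values were seen. In the other 9 splits of the libraries into 3 and 3, at most 2 transcripts were listed in this way. An FPKM of 0 can be a failed estimate, and the count was 17 without control replicate 1, 19 without poly(I:C) replicate 2 and 16 without poly(I:C) replicate 3, where fewer libraries have to meet the condition. The reverse count rose from 0 to 3 without control replicate 1, 5 without control replicate 2, 2 without poly(I:C) replicate 1 and 1 without poly(I:C) replicate 2, and was 28 above 0.1 FPKM.

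Whether the kind of lncRNA mattered was compared through the newly assembled genes deposited beside the lncRNAs. The exons of 4787 lncRNAs (43.81%) were identical to those of a transcript in that set. Of the tested transcripts with such a match 9.69% were called (44 called, 410 not), and of the others 9.22% (44 called, 433 not; odds ratio 1.06, Fisher's exact test, two-sided, p = 0.824, adjusted over the 2 tests 0.824). Among matched transcripts 38 rose and 6 fell, among the others 35 rose and 9 fell (odds ratio 1.63, Fisher's exact test p = 0.572, adjusted 0.824). No difference between the classes was detected, with or without any single library, but the odds ratio of rises to falls was 6.30, 9.37 and 6.20 without control replicates 1, 2 and 3 and 0.967 without poly(I:C) replicate 2.

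The called lncRNAs did not differ detectably in length from the other tested transcripts, except that with no filter on FPKM they were 277 bp longer (permutation test, adjusted p = 0.0284). Their median exonic length was 1198.5 bp against 1259 bp for the other 843 tested transcripts, a difference of -60.5 bp (permutation test with 100000 resamples, two-sided, p = 0.712, adjusted over the 2 tests 1). The mean exon number was 2.58 in both sets. The planned test of the median exon number could show no difference, because most lncRNAs have 2 exons. Within 3 equal-sized classes of mean FPKM the length differences were -25.5, -629 and -17.5 bp from the lowest to the highest class, with adjusted permutation p of 0.942, 0.717 and 0.942. Transcripts are not independent replicates in this comparison.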

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

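Chosen after the data were seen were the lncRNA class used, the covered-base filter, the 100 kb span limit, leaving out libraries from the count of lncRNAs listed at 0, and all fits of the share of a locus. None of the 88 called transcripts or 145 called loci that were tested under an alternative changed sign there. Of 415 values of named transcripts and loci under other fits, 50 lost their call and 0 reversed. The absence of reversals was largely fixed in advance, because the groups did not overlap at any called transcript or locus. Another pseudocount, filter, block or limma setting, or a library left out, could not have reversed their signs. The calls of 7 named rises, 2 named falls and all 8 named loci held in every other fit that tested them. MSTRG.110223 (limma adjusted p = 0.0109) does not pass 0.01. Its transcript and that of MSTRG.104681, with the same values, lost calls. The 100 kb span limit removed the 2 largest rises, MSTRG.92782.1 and MSTRG.76011.3 (spans of 247492 and 199089 bp), and their loci. With a mean of at least 1 FPKM, which left 376 transcripts and 437 loci, 23 transcripts (17 rose, 6 fell) and 50 loci (34 rose, 16 fell) were called. At an adjusted p below 0.01 there were 49 transcripts (46 rose, 3 fell) and 73 loci (66 rose, 7 fell). Requiring a doubling or halving left 8 falling transcripts, and 88 loci of which 10 fell, and without a filter 5 transcripts fell. Leaving out a library gave 53 to 67 transcripts (49 to 61 rose, 4 to 10 fell) and 94 to 130 loci (76 to 94 rose, 13 to 36 fell), with fewer samples. The lncRNAs listed at 0 in control numbered 99 above 0.1 FPKM and 3 above 1 FPKM, and 12 to 19 without a library. Those listed at 0 under poly(I:C) numbered 28 above 0.1 FPKM and 0 to 5 without a library.

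Several differences changed sign, and the cause was not tested. The length difference was 28 bp with a pseudocount of 0.1, 97 bp with a mean of at least 1 FPKM (both adjusted permutation p = 1) and 277 bp with no filter (adjusted permutation p = 0.0284), where it passed the threshold in the direction opposite to the main -60.5 bp. The odds ratio of a call between classes was 0.832 with a mean of at least 1 FPKM and 0.934 to 1.3 without a library, the lowest without control replicate 2. That of rises to falls was 0.822 with no filter and 0.967 to 9.37 without a library, the lowest without poly(I:C) replicate 2. The share of a locus was called for 1 transcript, for 6 with a pseudocount of 1, and for 0 to 2 without a library.

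With the replicate number as a replicate block, 57 transcripts (49 rose, 8 fell) and 146 loci were called. Among them were 54 of the 88 transcripts and 128 of the 145 loci of the main fit, and 5 named calls ended. An unadjusted p below 0.05 by limma was reached by 358 loci with the block and 304 without. The odds ratios were 1.02 and 8.59 and the length difference was -206 bp, none past the threshold. Deviations of same-numbered libraries correlated by 0.0412, 0.273 and 0.364. Control replicates 2 and 3 correlated best with their own number and control replicate 1 with poly(I:C) replicate 3 (0.0482), so the numbers were not taken as pairs, and whether same-numbered libraries share an animal or culture is unknown. The planned gene lists were not run under any setting. At the simulated depth, dispersion and 3 libraries per group, 2-fold changes were recovered for only 35.4% of transcripts and 23.9% of loci, and which of these set the limit was not tested.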

Other observations

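The tests of the share of a locus, of depth, of neighbouring loci, of reads moved between overlapping transcripts and of scaffolds, and the reading of the test of the scale's floor, were chosen only after the result was seen.

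A few loci held most of the summed FPKM, which is scaled by exonic length and so is not a share of the reads. MSTRG.101521 and MSTRG.101431 on chromosome 17 and MSTRG.1224 on chromosome 1 together took 74.7 to 92.2% of the summed FPKM of a library. Their transcripts are short: MSTRG.101431.2 has 267 bp of exons spread over 4071.5 kb, and MSTRG.1224.2 has 293 bp. MSTRG.101521.9 was at 39311 FPKM in control replicate 3 and below 1 FPKM in the other libraries. MSTRG.1224.2 was at 7379 and 5281 FPKM in poly(I:C) replicates 1 and 3 and listed at 0 in the other 4 libraries. Other abundant loci also varied between libraries, MSTRG.147826 on a scaffold from 8.79 to 2576 FPKM and MSTRG.109221 on chromosome 19 from 28.5 to 2071 FPKM. By contrast MSTRG.20571 on chromosome 3 was at 361 ± 1.50 FPKM in control and 305 ± 17.7 FPKM under poly(I:C), and MSTRG.127308 on a scaffold at 260 ± 13.8 and 290 ± 17.4 FPKM (SD, n = 3 each). Neither passed limma (adjusted p = 0.431 and 0.647), though the groups did not overlap at either locus.

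At MSTRG.113657 a candidate explanation for the fall of MSTRG.113657.1 is that less of its RNA kept the intron of 1681 bp under poly(I:C). Over 271 transcripts of 101 loci with several tested transcripts, limma on the share of the locus called only this transcript (log2 change -2.78, adjusted p = 0.0187), with 26 at an unadjusted p below 0.05, and called 0 without control replicate 1 or 3 or without poly(I:C) replicate 2 or 3. It held 44.9 to 63.2% of the locus in the control libraries and 4.04 to 6.65% in the poly(I:C) libraries. If the reads of the locus stayed the same in number, reads moved to the transcripts without the intron would give these at least the FPKM lost, since they are shorter. The mean gain was 28.97% of the mean loss, and the largest gain between any pair of libraries (8.20 FPKM) was below the smallest loss (13.9 FPKM). The part of the loss that the gain does not cover is, by construction, the fall of the locus sum. That sum went from 24.7 to 14.3 FPKM and did not pass (limma adjusted p = 0.0625). Gain and loss are thus no evidence separate from that fall. Only as far as the fall holds do they argue against moved reads alone. The same limit applies to a change in splicing alone, at an unchanged total of the locus. Moved reads together with a fall of the whole locus stay open. Open stay a change in splicing together with a fall of the whole locus, and a change in the decay of the RNA or in unspliced precursor RNA. None of these was tested. Of the 10 splits of the libraries, the real one included, 2 called as many transcripts (real 1, highest other 1), and 10 splits cannot give a share below 0.05.

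More of the called lncRNA loci rose than fell, which may be a response to poly(I:C) or come from the measurement. Over all 1062 tested loci the median log2 change was -0.0909, so the excess of rises holds for the calls only. Library scaling that shifts the medians, as the whole cause, is argued against by 66.67% of called loci that rose after centring each library on its median (lower 95% bound 58.6%). Centring moved the log2 changes little (MSTRG.92782 from 6.70 to 6.68), so the medians of the groups hardly differed. Quantile normalization, which gives all libraries the same distribution of values, called 148 loci, of which 101 rose and 47 fell. That argues against a difference in these distributions as the whole cause. Other scaling that leaves the medians in place was not tested. Depth, as recovered from the FPKM steps, is argued against by overlapping ranges and a ratio of 1.0033 between the group means. The floor of the log scale stays open: among 24 called loci with a mean of at least 2 FPKM 58.33% rose (exact binomial interval 36.6 to 77.9%), against 71.1% of the 121 others (Fisher's exact test p = 0.234). An earlier rule read any share near an even split as going with the floor, and it was replaced once this value was seen because the interval includes both an even split and the share of the others. The real split called 88 transcripts and 145 loci, the highest of the other 9 splits 4 and 2 (1 of 10 splits called as many in each case), and 10 splits cannot give a share below 0.05.

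Called loci that lie within 100 kb of each other changed in the same direction. All 7 such pairs among 224 tested pairs rose together, where permuted calls gave a mean of 2.37 pairs called in the same direction (share of permutations as high 0.0167). That count joins closeness with direction, and direction among pairs already called was not tested. Permuted calls gave a mean of 4.15 pairs with both called, so permuted pairs often shared their direction too. Called loci were not detectably closer than chance (7 pairs with both called, permutation p = 0.131). Moreover, 3 of the pairs come from MSTRG.102406, MSTRG.102411, which lies inside it, and MSTRG.102412 beside it on chromosome 17. Pieces of a single transcript assembled apart could give the 5 pairs on the same strand, where MSTRG.104682 also lies inside MSTRG.104681, and no value separates these. They cannot give the 2 pairs on opposite strands, MSTRG.9043 with MSTRG.9045 on chromosome 1 and MSTRG.91771 with MSTRG.91803 on chromosome 15, which all rose. Alone these 2 pairs were no more than permuted calls often gave (mean 0.906, permutation p = 0.230), so a shared response of neighbouring loci is a hypothesis that rests mainly on the pairs of the same strand.

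Transcripts of loci with several transcripts varied more between replicates than locus sums of matched level, with a difference in median SD of 0.0626 on the log2 scale (bootstrap 95% interval 0.0250 to 0.0902), as the division of reads among overlapping transcripts would give. The sums had a median SD of 0.270, against 0.236 for matched loci with a single transcript. Division among the transcripts of a locus alone would not give that second difference, which was not tested. Of loci on unplaced scaffolds 10.2% were called, against 15.0% of loci on chromosomes (Fisher's exact test p = 0.0459, adjusted over 6 tests 0.235).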
